A study of Gallus gallus with 3 samples.

How the data were processed

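Polyadenylated RNA of the spinal neural tube was sequenced from 2 HH14 libraries and 1 HH19 library, grouped by the stage in their labels. The expression values are TPM per Ensembl gene, deposited by the authors in 1 table with 1 column for the HH14 pair and 1 for HH19. Per the submitters' processing notes, the genome build was galGal4 and FastQC, SAMtools, TopHat2 and DESeq2 were used. Their roles, their versions, the counting tool and the way the HH14 libraries were merged are not given in the sources used here. The label of the HH19 library carries the dissection protocol written for HH14. The columns summed to 957153.8 TPM at HH14 and 946462.2 TPM at HH19, and were compared as deposited. The total reads per library are unknown. No coordinates were used, and gene names are those in the table.

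A limma test and camera set tests over 3 libraries had been planned. With 1 HH14 column neither could be run on the deposited values, and genes were described by size instead. Values were taken as log2(TPM + 1) with a pseudocount of 1, and genes with a mean TPM of at least 1 over the 3 libraries, the HH14 value counted for 2, were tested. A log2 difference of at least 1 either way counted as higher or lower. The median of each of 33 gene lists was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, for the 32 lists with at least 5 tested members.

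The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 named genes with the largest difference in each direction among those with at least 10 TPM at the higher stage. In each list it named the 4 members with the largest difference among those higher or lower and the 2 most abundant within 2-fold. It also allowed any member of the progenitor domain, motor neuron, interneuron, HOX and neural crest lists, and the 5 most abundant genes. A symbol on several rows was taken from the row with the highest mean. Some genes that the rule named are not reported here, but they stay in all counts and list values.

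Values per HH14 library were recovered for low genes. Low values in the HH19 column were whole multiples of the value of 1 read, after 1 added read, and those in the HH14 column stepped as the mean of 2 libraries. In 1426 genes without a read in any library the ratio of the columns was 1.066. A whole number of pooled reads explained only 208 of 1038 low HH14 values (20%). Library A gave 56.16% and library B 43.84% of the HH14 value of 1 read. For each gene up to 400 HH19 reads were searched for a combination of whole reads in the 3 libraries. A gene was kept where at most 0.003 solutions were expected by chance, 1 read was worth at most 0.2 TPM and the mean TPM was below 20. These limits were chosen after differences between the libraries had been seen, and chance limits of 0.001 and 0.01, 1-read values of 0.15 and 0.3 TPM, and no limit on 1-read value or mean were tried as well. In all, 4907 genes (30.8%) were recovered, 1187 of them with a mean TPM of at least 1. When the ratio of the columns was perturbed, in 3 runs, 12.3 such genes were recovered on average (1.04%). List values per HH14 library used recovered genes with at least 20 reads (2476 genes) as log2 ratios. Sampling of reads alone was simulated 100 times.

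limma with an intensity trend was run on the recovered genes, two-sided with Benjamini-Hochberg adjustment, at an adjusted p below 0.05 and a 2-fold minimum. This test was added after the data were seen, and nothing shows that the pools were of separate egg batches, so its p-values measure only the spread between these libraries.

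The steps were tested on simulated data for HH19 against HH14 with 15916 genes, 200 of them changed 4-fold, and a dispersion of 0.02. Of 6182 recovered genes 99.94% had the right library values, and of 1834 with a mean TPM of at least 1, 99.78%. The size rule found 193 of the 200 changed genes and 3 unchanged ones. limma called all 19 changed genes among the 1834 and 3 unchanged ones. Of 200 unchanged lists 6% lay outside the central 95% of random lists. The simulated HH14 libraries shared 1 level per gene. In the data 9.6% of recovered genes with a mean TPM of at least 1 were at least 2-fold apart between the HH14 libraries. These counts of right and wrong calls therefore do not carry over to the data. The alternatives were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, median-ratio scaling, quantile normalization and leaving out each HH14 library among recovered genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.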

Results

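RNA-seq was carried out on the spinal neural tube of White Leghorn chicken embryos at 2 Hamburger-Hamilton stages, HH14 (2 libraries) and HH19 (1 library). The spinal neural tube is the epithelium that gives rise to the spinal cord. Per the labels, it was taken at brachial level and further back toward the thorax, and surrounding mesoderm, endoderm, notochord and surface ectoderm were removed by hand, partly after trypsin. Each library held tissue of about 25 embryos. Expression was given as TPM, a length-normalized share of all transcripts, for 15916 genes, of which 2699 had no symbol. The HH14 libraries shared 1 column, so the HH14 values below are the authors' single values and carry no replicate error. For the comparison of the stages no test could be run on these columns. Genes were described by size: a gene was called higher or lower at HH19 when its log2(TPM + 1) differed by at least 1 and its mean TPM over the 3 libraries was at least 1. Log2 differences below are on the log2(TPM + 1) scale, which understates the change of low genes. TPM keeps no read total, and the absolute depth of the libraries is unknown. No gene was at 0, because the lowest values step as if 1 read had been added per gene and library. The steps between the lowest values gave relative depths, and the deeper HH14 library, denoted library B, had 1.28 times the depth of the other, library A. For some low genes the value in each HH14 library could be recovered, and HH19 was compared with library B alone after the data were seen. Of 19 recovered genes that were named or in a list and called higher, 15 were at least 2-fold above library B on the log2(TPM + 1) scale, and of 9 called lower 3 were at least 2-fold below it. Without a pseudocount, in plain TPM, it was all 19 and 7 of the 9, the exceptions being APOA1 and HOXD8.

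The comparison of HH19 with HH14 asks how the expression of cell identity regulators and other genes in the neural tube differed between the stages. At least 2-fold higher at HH19 were 19 of 33 tested neuronal differentiation genes, 6 of 14 motor neuron genes and 8 of 10 interneuron class transcription factors. The filter on mean TPM left out most of the 26 measured interneuron factors, and low genes could pass it through their HH19 value. CACNG3 had 1.11 TPM at HH14 and 42.6 TPM at HH19. HOXA9, HOXB9 and CDX4 were lower, with HOXB9 at 495 and 45.9 TPM, as were 2 of 13 surface ectoderm genes and 4 of 7 endoderm and lateral plate genes. Against library B alone the surface ectoderm list lay inside the central 95% of random lists (percentile 5.28), and none of those 4 genes met the size rule. Of 21 neural crest genes 5 were lower and 3 higher. Of the 11097 genes tested, 436 were at least 2-fold higher at HH19 and 153 at least 2-fold lower, and 10508 (94.7%) lay within 2-fold. Higher genes were 74% of those that differed, and 60.6% after quantile normalization of the 2 columns, which gave 314 higher and 204 lower. The counts also depended on the pseudocount, with 279 lower genes at a pseudocount of 0.1 and 149 higher and 46 lower at 5, and on the filter, with 261 higher and 85 lower at a mean TPM of at least 5. The median log2 difference of all tested genes was 0.052, and the values of the stages correlated across genes with r = 0.972 and rho = 0.971, genes not being independent replicates.

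**Figure D1:**
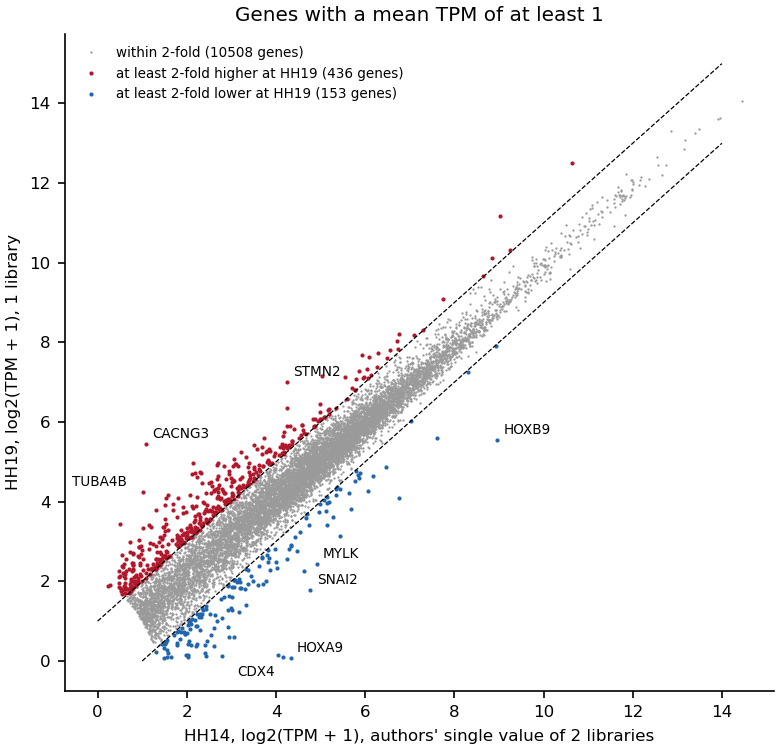
Expression of the 11097 tested genes as log2(TPM + 1) at HH14 (x axis, the authors' single value for 2 libraries) and at HH19 (y axis, 1 library), with dashed lines at a 2-fold difference. The 436 red genes lie above the upper line and the 153 blue genes below the lower one, with HOXB9 at 495 TPM at HH14 and 45.9 TPM at HH19.

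The 10 largest differences toward HH19, among genes with at least 10 TPM there, were in CACNG3, TUBA4B, SCRT2, STMN2, C8orf46, ROBO3, UTS2B, RAMP1, LHX5 and GPC3. CACNG3, a voltage-gated calcium channel gamma subunit, had 1.11 TPM at HH14 and 42.6 TPM at HH19 (log2 difference 4.37). STMN2, a microtubule regulator of growing axons, had 17.9 and 127 TPM (2.76), and SCRT2, a zinc finger factor of newly born neurons, 3.38 and 30.5 TPM (2.84). ROBO3, a receptor of commissural axons, had 2.0 and 16.9 TPM (2.57). The 10 largest differences toward HH14 were in HOXA9, CDX4, HOXB9, SNAI2, MYLK, SOX10, DACT2, PTN, GREB1L and ARHGAP28. PTN, a secreted growth factor, had 195 TPM at HH14 and 47.6 TPM at HH19 (log2 difference -2.01). MYLK, the myosin light chain kinase, had 29.2 and 4.37 TPM (-2.49). The 5 most abundant transcripts were COX1, COX3, COX2, EEF1A1 and ND1, all within 2-fold.

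Of 33 tested neuronal differentiation genes, 19 were at least 2-fold higher at HH19 and 0 lower. Their median log2 difference was 1.11, at the 100th percentile of 10000 random lists matched on expression. TUBB3, the neuronal beta tubulin, had 213 TPM at HH14 and 540 TPM at HH19, MYT1 2.49 and 16.2 TPM, and STMN3 3.97 and 25.3 TPM. NCAM1, with 132 and 193 TPM, and CRMP1, with 134 and 195 TPM, were the most abundant members within 2-fold. The neurofilament genes NEFM (59.5 and 203 TPM) and NEFL (46.0 and 138 TPM) were also higher. TUBB3, NEFM and NEFL were chosen after their values were seen. Of 24 synaptic and transmitter genes, 5 were higher and 0 lower (median 0.55, percentile 99.97), among them SYT4 (0.898 and 6.32 TPM) and CPLX2 (5.43 and 22.6 TPM). Of 36 axon guidance genes, 5 were higher and 3 lower, with a median of 0.22 at percentile 92.56. ROBO3 and CNTN2 (6.99 and 23.2 TPM) were among the higher ones, and SEMA3A (11 and 2.76 TPM) was among the lower ones.

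Of 14 tested motor neuron genes 6 were higher and 0 lower (median 0.88, percentile 100), among them ISL1, LHX3, ONECUT3, LHX4 and CRABP1. ISL1, a LIM homeodomain factor of motor neurons, had 2.25 TPM at HH14 and 12.9 TPM at HH19, moving from rank 9917 to rank 7078 of all genes. LHX3 had 4.80 and 17.7 TPM, while SLIT3 and CHRNB4 lay below their HH14 values. Of 10 tested interneuron class transcription factors 8 were higher and 0 lower (median 1.42, percentile 100). The 10 were those of 26 measured members that passed the filter on mean TPM, which low genes could pass through their HH19 value. The share of 8 in 10 therefore does not hold for all members. With no filter the list also lay at percentile 100. LHX5 had 1.47 and 12.9 TPM and LHX1 4.65 and 21.0 TPM, both LIM homeodomain genes of interneurons. LMX1B, at 13.7 and 8.39 TPM, was within 2-fold. The HH14 libraries themselves differed in motor neuron genes, where their values could be recovered, with a median log2 ratio of 1.21 between the deeper and the shallower library.

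**Figure D2:**
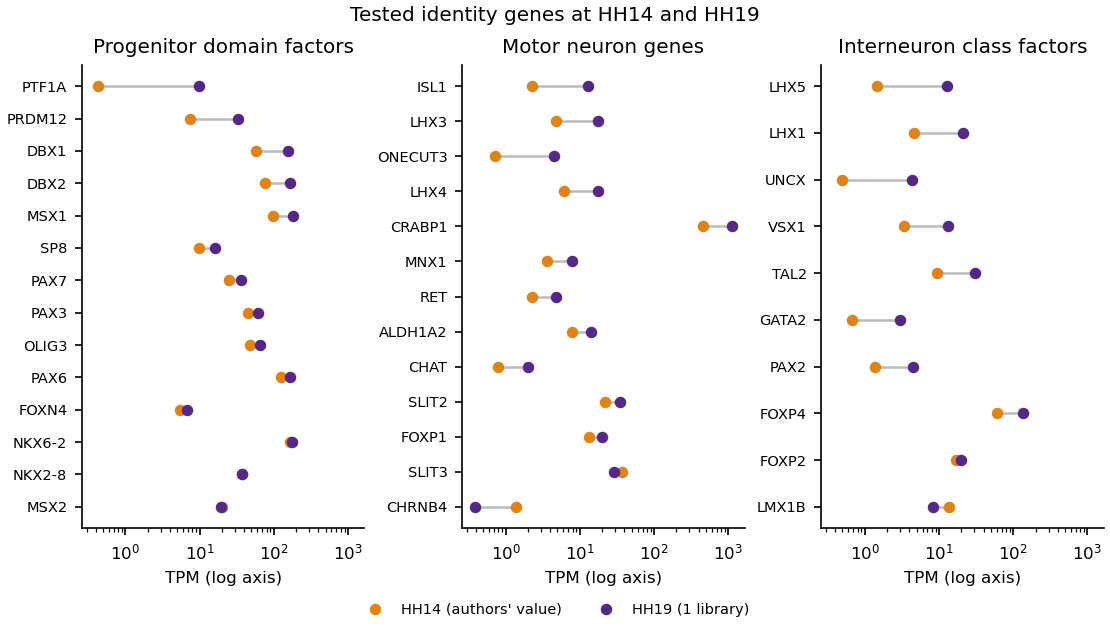
TPM on a log axis of tested progenitor domain, motor neuron and interneuron class genes, without those not reported here, at HH14 (orange, the authors' single value) and at HH19 (purple, 1 library), joined by a grey line per gene. PTF1A moves from 0.424 to 9.76 TPM, LHX5 from 1.47 to 12.9 TPM, and NKX2-8 stays at 36.9 and 36.8 TPM.

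Of 14 progenitor domain transcription factors 4 were higher and 0 lower (median 0.49, percentile 99.96). They were PTF1A (0.424 TPM at HH14 and 9.76 TPM at HH19), PRDM12 (7.34 and 32.6 TPM), DBX1 (57.2 and 155 TPM) and DBX2 (76.4 and 165 TPM), which mark dorsal and intermediate domains. PAX6 had 125 and 166 TPM, and NKX6-2 165 and 176 TPM. All 19 tested pan-neural progenitor genes lay above their HH14 value (median 0.72, percentile 100), and 2 of them, SOX9 (7.45 and 29.9 TPM) and ZIC1 (28.4 and 59.2 TPM), by at least 2-fold. SOX2, a general neural progenitor factor chosen after its values were seen, had 178 and 185 TPM. Of 9 floor plate genes 1 was higher, FERD3L (5.10 and 18.2 TPM), and 0 lower (median 0.67, percentile 99.98). FERD3L had 1.42 TPM in HH14 library A and 8.78 TPM in library B, and against B alone its log2 difference was 0.98, or 2.08-fold in TPM. SHH had 88.3 and 117 TPM. Of 12 roof plate genes 1 was higher and 0 lower (median 0.08, percentile 50.41). Of 10 glial and late radial glia genes 2 were higher, SOX9 and FGFR3, and 1 lower, SOX10 (median 0.37, percentile 97.79). That list lay inside the central 95% of random lists with no filter on low values (percentile 88.34) and at pseudocounts of 0.1 (96.92) and 5 (96.02). Its 9 recovered members had a median log2 ratio of 0.10 for HH19 over library B (percentile 20.2) and -0.08 over library A.

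Of 25 retinoic acid and FGF pathway genes 7 were higher and 0 lower (median 0.38, percentile 99.89, but 87.12 with no filter and 96.32 at a mean TPM of at least 5), including FGF18 (0.913 and 6.32 TPM), RXRA (12.9 and 37.5 TPM) and FGFR3 (54.2 and 135 TPM). The 9 recovered members, low genes tested or not, had a median log2 ratio of -0.13 for HH19 over library B (percentile 10.56) and -0.28 over library A, with 4 above each library. Of 20 Notch pathway genes 2 were higher, HEYL (10.3 and 42.0 TPM) and DLL4 (2.93 and 7.48 TPM), and 0 lower (median 0.48, percentile 100). Of 12 Hedgehog pathway genes 1 was higher, BOC (16.8 and 48.8 TPM), with a median of 0.20 at percentile 93.35. WNT pathway genes had 3 higher and 2 lower of 27 (median 0.10, percentile 72.63), with WNT7A at 3.86 and 11.9 TPM and DKK1 at 1.96 and 0.210 TPM. BMP and TGF-beta pathway genes had 0 higher and 1 lower of 22, BMPR1A at 34.2 and 14.7 TPM (median 0.06, percentile 47.7).

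Cell cycle genes stayed within 2-fold. None of the 42 tested differed by 2-fold (median -0.11, percentile 9.87), with PCNA at 1739 and 1459 TPM and HMGB2 at 940 and 895 TPM. Of 8 cyclin dependent kinase inhibitors and cycle exit genes 0 were higher or lower, but their median was 0.46 at percentile 99.56, or 82.89 with no filter, with BTG1 at 306 and 437 TPM. No ribosomal protein gene (62 tested, median -0.05, percentile 87.99), oxidative phosphorylation gene (35 tested, median -0.10, percentile 30.72) or glycolysis and hypoxia gene (26 tested, median 0.14, percentile 98.83) differed by 2-fold. Of 24 epigenetic regulator genes 1 was higher and 0 lower (median 0.02, percentile 39.45), with HDAC2 at 761 and 620 TPM. Extracellular matrix genes had 3 higher and 1 lower of 22 (median -0.03, percentile 21.01), with POSTN at 6.0 and 18.1 TPM. Among stress response and immediate early genes 0 of 18 were higher and 1, HMOX1 (56.7 and 24.5 TPM), was lower (median 0.22, percentile 95.96).

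The HOX genes that could be tested divided by paralog group. Of 39 listed, 26 were matched by symbol, with no HOXC gene and no HOXB8 among them. Of the 15 tested, 3 were at least 2-fold higher (HOXD4, HOXB5 and HOXB4) and 3 at least 2-fold lower (HOXA9, HOXB9 and HOXD8), so that the median of 0.59 (percentile 100, but 82.88 with no filter) and the mean of -0.10 differ in sign. All 12 genes of groups 1 to 7 lay above their HH14 value (median 0.64), 11 of them after median-ratio scaling, and all 3 of groups 8 and 9 lay below it (median -3.40). This division was made after the values were seen. Against library B alone HOXD8 was under 2-fold lower (log2 difference -0.56, or 1.78-fold in TPM), with 11.1 TPM in library A and 2.71 TPM in B. Among HOX genes too low to be tested, HOXD9 had 1.34 TPM in A and 0.227 TPM in B. HOXD10 had 0.474 and 0.0411 TPM, and HOXA10 0.147 and 0.0383 TPM, where the B values of both are those of a gene without a read. These low genes had 0 recovered reads at HH19. HOXD8, HOXD9 and HOXD10 thus already differed between the HH14 libraries, with higher values in A. For HOXA10 the reads in A were too few to tell. HOXB4 had 396 and 805 TPM, and HOXB9 495 and 45.9 TPM, moving from rank 245 to rank 3319. HOXA9 had 19.1 TPM at HH14 and 0.0488 TPM at HH19 on the most abundant of the 3 rows with its symbol. Caudal progenitor and early embryonic genes had 1 higher and 4 lower of 15 (median -0.37, percentile 0.01). The 5 recovered members, tested or not, lay inside the central 95% of random lists for HH19 over library B (percentile 10.39). The lower genes of this list were CDX4 (16.8 and 0.0707 TPM), CDX2 (2.53 and 0.687 TPM, with -0.65 against library B alone), PRTG (487 and 241 TPM) and LIN28A (129 and 63.7 TPM), the last chosen after its values were seen. Brachyury (T), a tail bud and notochord gene, had 5.72 and 5.70 TPM.

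**Figure D3:**
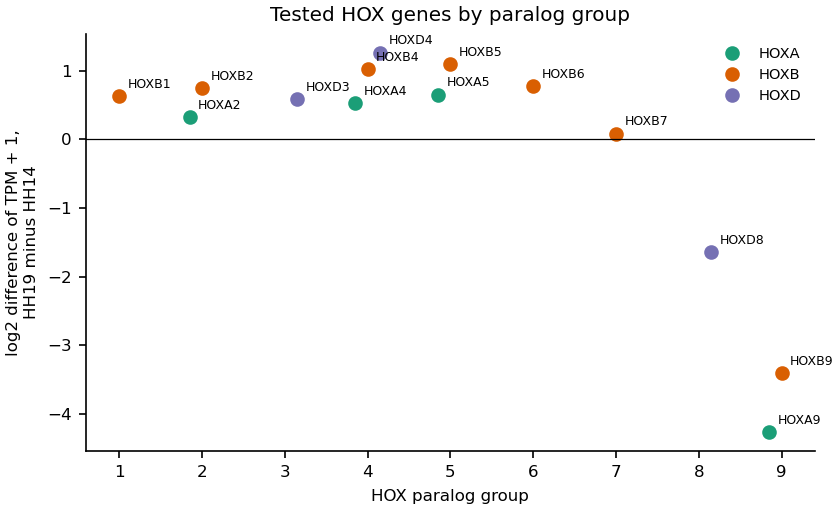
Log2 difference of TPM + 1 between HH19 and HH14 (y axis) of tested HOX genes by paralog group (x axis), coloured by cluster, 1 point per gene, without those not reported here. All plotted genes of groups 1 to 7 lie above 0, where 11 of the 12 tested stay after median-ratio scaling, while HOXD8, HOXB9 and HOXA9 lie at -1.65 (-0.56 against HH14 library B alone), -3.40 and -4.26.

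Neural crest genes went both ways. Of 21 tested, 5 were lower at HH19 and 3 higher (median -0.27, percentile 0.05, but 10.81 with no filter on low values). The lower ones were SNAI2 (26.3 and 2.45 TPM), SOX10 (23.8 and 3.76 TPM), ITGA4 (34.5 and 9.59 TPM), TFAP2A (8.81 and 2.48 TPM) and EDNRB (8.10 and 2.54 TPM). MSX1 and PAX7, dorsal genes shared with the progenitor list, had 98.5 and 181 TPM and 24.9 and 36.2 TPM. The 6 recovered members, low genes tested or not, had a median log2 ratio of 0.79 for HH19 over library B (percentile 91.0) and 0.86 over library A, and 4 of them lay above each library. Of the 5 lower genes only TFAP2A was among these 6, and it lay at least 2-fold below each library. These medians thus do not check the differences of SNAI2, SOX10, ITGA4 and EDNRB. FOXD3, also listed, was not matched by symbol. The higher ones among the 21 were SOX9, SOX8 (2.70 and 7.97 TPM) and ETS1 (5.91 and 12.9 TPM), of which SOX9 is also a neural progenitor gene. TFAP2A is shared with the surface ectoderm list, whose median was also below that of random lists. Sensory ganglion genes had 3 higher (ISL1, PRDM12 and NEUROD1) and 1 lower (EYA1) of 6 tested (median 0.59, percentile 96.95, and 99.14 at a pseudocount of 0.1). NEUROD1 differed from library B alone by 0.83, or 2.63-fold in TPM.

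Some markers of tissues that the dissection removed differed between the stages. Of 13 tested surface ectoderm genes 2 were lower at HH19 and 0 higher (median -0.61, percentile 0), WNT6 (4.71 and 1.27 TPM) and TFAP2A, while EPCAM had 74.2 and 47.6 TPM. Against library B alone this list lay inside the central 95% of random lists, since its 10 recovered members had a median log2 ratio of -0.13 at percentile 5.28 and 5 of them lay above B. Against library A the median was -1.96. WNT6 was at -0.97 against library B, or 2.72-fold lower in TPM. Of 7 endoderm and lateral plate genes 4 were lower and 0 higher (median -1.07, percentile 0), among them HAND1 (4.41 TPM, and 0.0812 TPM with 0 recovered reads at HH19), APOA1 (8.23 and 2.56 TPM) and CDX2. APOA1 had 13.6 TPM in library A and 2.82 TPM in library B, and against B alone it differed by -0.10. Against B alone HAND1 differed by -0.57 and CDX2 by -0.65 on the log2(TPM + 1) scale, where the pseudocount of 1 shrinks differences near 1 TPM. In plain TPM CDX2 was 2.39-fold lower, and HAND1 had 0.601 TPM (8 reads) in B and 0 reads at HH19. The 10 recovered members still lay below random lists against library B (median -0.87, percentile 0). CDX2 is also in the caudal list. Paraxial mesoderm and muscle genes had 1 higher, UNCX, which is also an interneuron gene, and 2 lower of 10, MEF2C and TNNC1 (median -0.03, percentile 19.57). Endothelial genes had 1 higher, ESAM (0.86 against library B alone, or 2.37-fold in TPM), and 0 lower of 8 (median -0.11, percentile 8.78), notochord genes 0 higher and 1 lower of 5 (median -0.004, percentile 31.75, but 1.64 with no filter). HBG1 and HBE, the tested blood cell genes, had 15.2 and 23.6 TPM and 6.25 and 6.63 TPM. In all, 13 of the 32 lists with at least 5 tested members lay above the central 95% of random lists and 4 below it. With no filter on low values 9 lay above it, and after quantile normalization 14. By chance 1.6 lists would lie outside if genes and lists were independent, but the lists share members. Between the HH14 libraries 4 of 13 lists of recovered genes also lay outside, so the number of lists does not single out stage.

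**Figure D4:**
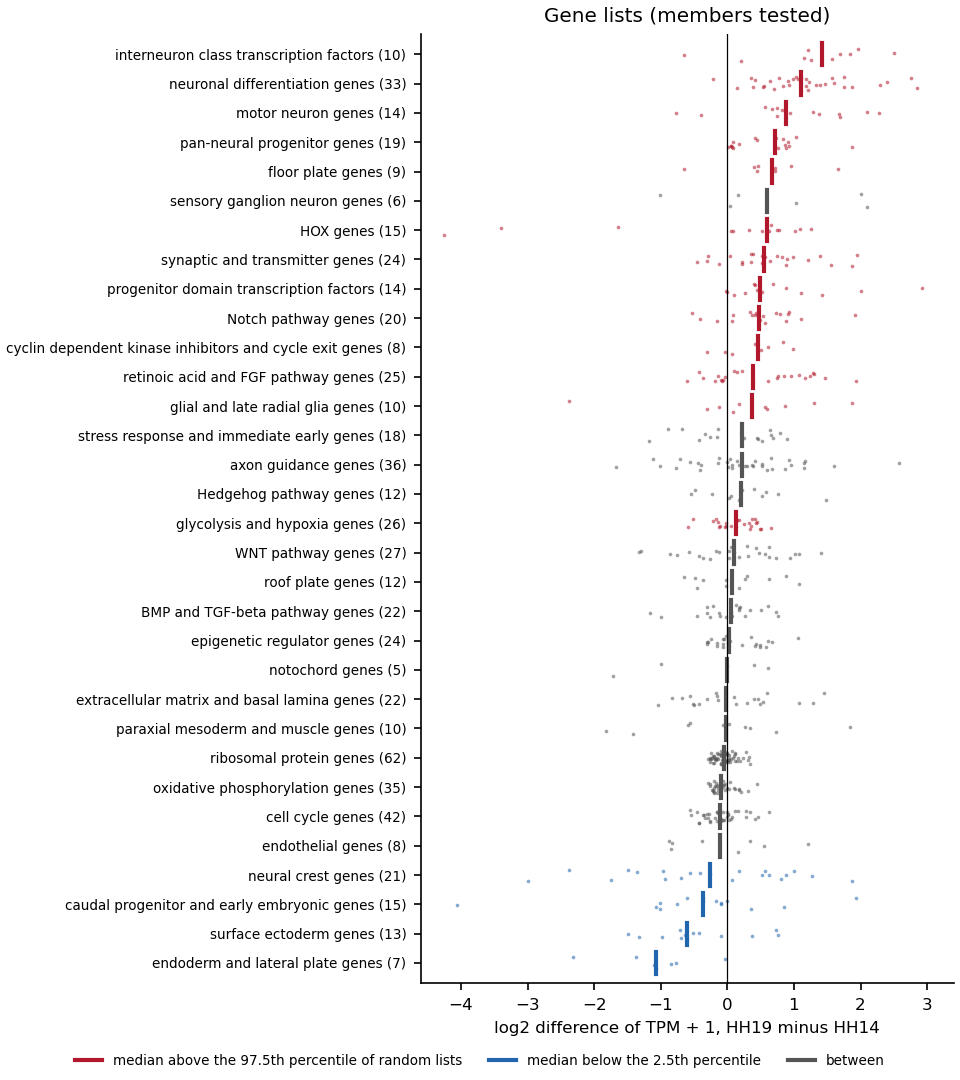
Log2 difference of TPM + 1, HH19 minus HH14, of each tested member (points) and the median (bar) of the 32 gene lists with at least 5 tested members, whose number stands in parentheses. The 13 red lists have medians above the central 95% of random lists (9 lists with no filter on low values), from interneuron class transcription factors at 1.42 down to glycolysis and hypoxia genes at 0.14, and the 4 blue ones lie below it.

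The 2 HH14 libraries were told apart at low read numbers, because low values lay on whole-read steps. For 1187 of the tested genes (10.7%, median mean TPM 2.13) the TPM of each HH14 library was recovered, and about 12.3 of them would be recovered by chance. The limits of this recovery were set after the differences between the libraries had been seen. Neither library could be tied to a replicate number. The libraries differed from each other as much as library B differed from HH19. The SD of the log2 difference was 0.62 between A and B, 0.55 between B and HH19 and 0.84 between A and HH19, and 114, 112 and 254 genes were at least 2-fold apart. Sampling of reads alone gave an SD of 0.21 between A and B in 100 simulations.

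HH19 lay at least 2-fold above each HH14 library for 71 recovered genes and below each for 7. Of 114 recovered genes called higher from the deposited HH14 value, 71 were at least 2-fold above each library, but of 39 called lower only 7 were at least 2-fold below each. Without library A the counts were 95 higher and 17 lower, and without library B 178 higher and 76 lower. After median-ratio scaling HH19 lay above each library for 37 genes and below each for 15. The 71 included PTF1A, UNCX, PAX2, GATA2, ONECUT3, SYT4 and FGF18. The 7 were TFAP2A, COCH, MEF2C, CAV1, AvBD10, CA13 and MYL3, of which COCH, AvBD10, CA13 and MYL3 were named after their values were seen. TFAP2A had 9.90 and 7.72 TPM in the HH14 libraries and 2.48 TPM at HH19. limma on log2(TPM + 1) of the recovered genes called 0 genes at an adjusted p below 0.05 with a 2-fold minimum (lowest adjusted p = 0.522), with 108 at an unadjusted p below 0.05, where 59.4 would be expected. Without the filter on low values limma called 50 genes higher and 11 lower among 4907. This test has 1 residual degree of freedom and assumes that the lone HH19 library varies like the HH14 pair. With library A taken as the lone library nearly as many genes passed the unadjusted threshold, so that excess is not particular to stage.

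Of the 13 lists with at least 5 recovered members, 4 lay outside the central 95% of random lists for library B over A. Among recovered genes with at least 20 reads, 6 of 8 motor neuron genes were higher in B (median log2 of B over A 1.21, percentile 99.9), as were 7 of 10 interneuron class transcription factors (0.71, percentile 97.94). Under the other recovery limits the interneuron list lay inside the central 95% at 4 of 5, with percentiles of 92.02, 95.91, 97.18 and 97.48, and outside it at the chance limit of 0.01 (98.3). MNX1, a motor neuron homeodomain gene, had 0.840 TPM in A, 6.28 TPM in B and 7.73 TPM at HH19. UNCX had 0.107, 0.889 and 4.39 TPM. All 10 recovered surface ectoderm genes were higher in A (median -1.06, percentile 0.1), as were all but 1 of 10 endoderm and lateral plate genes (-1.56, percentile 0). KRT14, an epidermal keratin chosen after its values were seen, had 3.17 TPM in A, 0.421 TPM in B and 0.833 TPM at HH19, and HAND1 8.21, 0.601 and 0.0812 TPM. HOXD8 had 11.1, 2.71 and 1.52 TPM, and CDX2 3.42, 1.64 and 0.687 TPM. For HH19 over library B the motor neuron, interneuron and synaptic lists lay above random lists, at percentiles of 99.46, 99.96 and 99.98. For B over A the 6 recovered neural crest genes had a median of 0.37 at percentile 79.98, and 23 synaptic and transmitter genes 0.08 at percentile 71.25. Values per HH14 library of HOXB9, CDX4, SOX10, SNAI2, ITGA4, EDNRB and the HOXA9 row used were not recovered under the limits used. Their differences could therefore not be checked against each HH14 library.

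**Figure D5:**
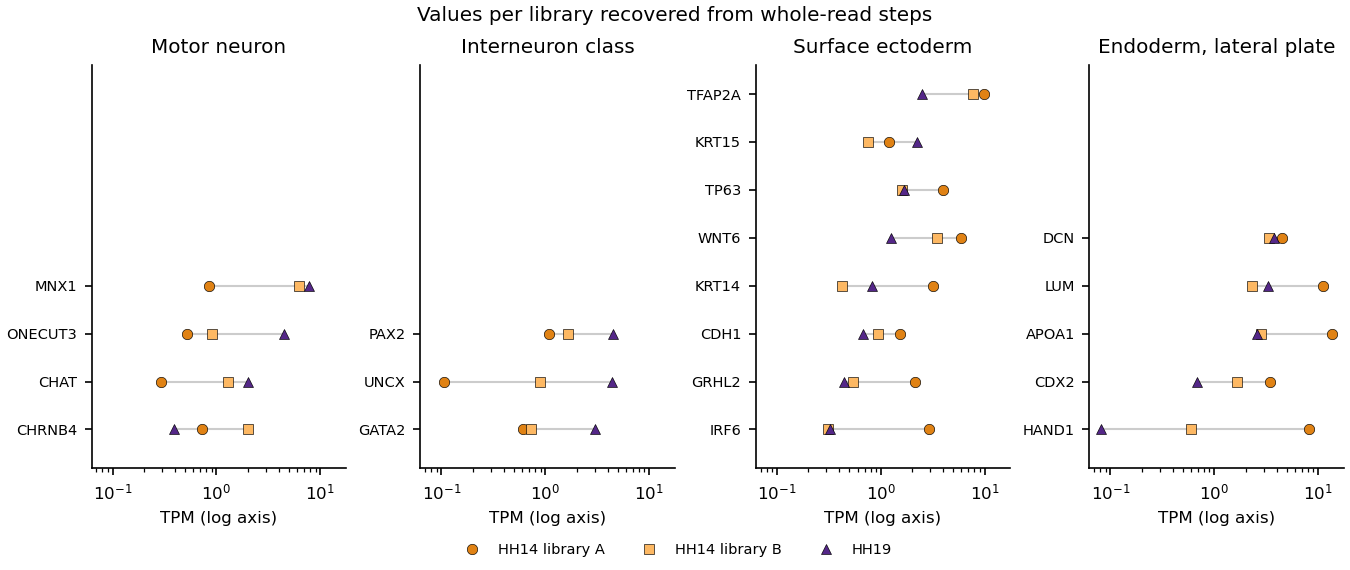
TPM on a log axis of tested and recovered members of 4 lists, without those not reported here, in HH14 library A (circle), HH14 library B (square) and HH19 (triangle). MNX1 has 0.840, 6.28 and 7.73 TPM in the 3 libraries and HAND1 8.21, 0.601 and 0.0812 TPM, so that library B lies nearer to HH19 than library A does for both genes.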

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

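The recovery limits, limma on recovered genes, quantile normalization of the recovered values, the unfiltered and median-ratio counts between libraries A and B, and the comparison of called genes with each HH14 library, with and without a pseudocount, were chosen after seeing the data. Of 218 named genes 40 moved under some setting of the deposited columns, as did 23 of 32 list medians. No gene higher or lower by 2-fold and no list outside the central 95% changed sign. Calls of lists did end: with no filter 9 lists lay above the central 95% instead of 13, without the HOX, cycle exit, retinoic acid and FGF, and glial lists, and below the central 95% the notochord list (percentile 1.64) took the place of the neural crest list (10.81). Signs did change near 0, for NTRK3, MITF, EYA2 and HBE among the genes reported here and for the paraxial mesoderm, extracellular matrix, roof plate, epigenetic and BMP lists. Genes lower at HH19 numbered 279 at a pseudocount of 0.1, and at a pseudocount of 5 there were 149 higher and 46 lower. At a mean TPM of at least 5 there were 261 higher and 85 lower, with fewer genes tested, and 2 lists lay below the 2.5th percentile. These were the neural crest and caudal lists, while the surface ectoderm list and the endoderm and lateral plate list had too few members left to be placed. Among recovered genes, HH19 lay above each HH14 library, HH19 lay below each, and libraries A and B lay apart, for 132, 44 and 300 genes at a pseudocount of 0.1, for 13, 0 and 9 at 5, and for 12, 1 and 29 at a mean TPM of at least 5. HH19 lay above and below each for 37 and 15 genes after median-ratio scaling and for 34 and 19 after quantile normalization. With no limit on 1-read value or mean the 3 counts were 110, 16 and 219. Leaving out library A or B gave 95 to 178 genes above and 17 to 76 below, each compared with a single library. limma called 50 genes higher and 11 lower without the filter and 0 in every other setting run. For the pseudocount, the scaling and limma, the cause was not tested. Camera was not run, and the eBayes and threshold alternatives and leaving out a library were run on recovered genes only, since the deposited columns hold 1 value per stage. No paired analysis was possible because the columns carry no replicate numbers. The recovered values cover low genes only, under limits that include a search up to 400 HH19 reads and a mean TPM below 20.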

Other observations

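All tests in this part were chosen after the result was seen, and so were the genes named in this paragraph and the next. Several genes outside the lists lay above each HH14 library at HH19. HCRT, the orexin precursor, had 1.83 and 1.84 TPM in the HH14 libraries and 14.2 TPM at HH19. The homeobox genes HMX2 and HMX3 had 0.0426 and 0.299 TPM, and 0.232 and 0.679 TPM, in HH14 libraries A and B, and 2.71 and 4.24 TPM at HH19. CDK5R2, a neuronal activator of CDK5, had 0.340, 1.68 and 9.14 TPM.

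All 13 mitochondrially encoded mRNAs were lower at HH19 (median log2 difference -0.30), making up 11.3% of the HH14 column and 9.35% of the HH19 column. After quantile normalization 10 of the 13 were lower (median -0.14). A row named for FOXD3, a neural crest factor, had 19.3 TPM at HH14 and 6.42 TPM at HH19. It was not matched by symbol, so the list values leave it out. Of rows without a symbol, ENSGALG00000028371 had 518 and 2295 TPM and ENSGALG00000026989 had 108 and 15.9 TPM.

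The 2 HH14 libraries differed as much as library B and HH19 did. Counting error of few reads is argued against, since 4 of 13 lists lay outside the central 95% of random lists (exact binomial p = 0.0031, treating lists as independent), and 4 of 16 (p = 0.007), 3 of 12 (p = 0.0196) and, at each of 2 limits, 3 of 13 (p = 0.0245) did so under other recovery limits, although at a chance limit of 0.001 it was 2 of 9 (p = 0.0712). More adhering tissue of every kind in library A is argued against for the recovered low genes only. Paraxial mesoderm and endothelial genes had a median log2 ratio of B over A of 0.22 (22 genes, 95% bootstrap interval -0.30 to 0.69). Surface ectoderm, endoderm and lateral plate genes had -1.19 (20 genes, -2.15 to -0.55). These intervals resample genes, not pools. The paraxial set holds UNCX, also an interneuron gene and higher in B, while its member MEF2C was higher in A. Whether library B is an HH19 library stays open. The motor neuron, interneuron and synaptic lists had a lowest percentile of 99.46 for HH19 over B. This cannot decide it, because such percentiles also arose between the libraries labelled HH14. For B over A the motor neuron list lay at 99.9 and the interneuron list at 97.94, although the synaptic list lay at 71.25. With HH19 as the lone library limma gave the most genes at an unadjusted p below 0.05 of the 3 choices. Library A as the lone one gave nearly as many and library B far fewer. HH19 thus stood out from the HH14 pair little more than library A did from the others. Also, 3 choices are too few for a share under 0.05. A different age or level of the HH14 pools, or adhering ectoderm and lateral plate alone, may play a part and was not tested.

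Among the tested HOX genes, none of them of the HOXC cluster, groups 8 and 9 lay below and groups 1 to 7 above their HH14 values. A single scaling factor between the columns moves genes alike and adds no spread, so it cannot be the whole cause. The SD of the log2 difference over all 15 tested HOX genes, without a division into groups, was 1.67, and 1.62 with library B alone for recovered genes. The central 95% of random matched lists reached up to 0.69. This comparison adds no separate support, because HOXA9 and HOXB9 had already been seen among the largest differences. More tail bud tissue in the HH14 pools stays open. The caudal list without CDX genes had a median of -0.17 (13 genes, 95% bootstrap interval -0.60 to -0.00). This cannot decide it, because the list mixes caudal progenitor with early embryonic genes. Brachyury (T), a tail bud and notochord gene, had 5.72 TPM at HH14 and 5.70 TPM at HH19, but it is a single gene. HOXD8 and the low, untested HOXD9 and HOXD10 were also higher in HH14 library A than in B. For these genes the difference was therefore not particular to stage, and HOXB9 and the HOXA9 row used could not be checked this way. A shift in axial level between the pools, and stage itself, may also account for the division by paralog group and were not tested.

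The neural crest list had a median log2 difference of -0.27, below random lists (percentile 0.05) but not with no filter on low values (10.81). Its 6 recovered members, low genes tested or not, had medians of the other sign, 0.79 over library B and 0.86 over library A, with 4 of 6 above each. Among the genes lower by at least 2-fold only TFAP2A was recovered, and it lay below each library. These medians thus cannot check the fall of SNAI2, SOX10, ITGA4 and EDNRB. Less adhering tissue of every kind at HH19 stays open, as paraxial mesoderm, endothelial and blood genes had a median log2 difference of 0.05 (20 genes, 95% bootstrap interval -0.57 to 0.34). Departure of crest cells from the neural tube between the stages is a biological hypothesis that may play a part and was not tested.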
